A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

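The series used f5C-seq on poly(A)+ RNA of Saccharomyces cerevisiae (budding yeast) grown overnight in rich medium at 28 °C. Pyridine borane reduces 5-formylcytidine (f5C), an oxidised form of 5-methylcytidine, to dihydrouridine, which reverse transcriptase reads as U. A modified cytidine is thus seen as a mismatch in treated RNA and as a normal base in untreated RNA. Per the labels' protocols, the treatment of the mRNA fragments lasted 24 h at 37 °C and pH 5.2, at a reagent concentration of 0.9 M, and the libraries were directional. There were 2 treated libraries and 2 input libraries, numbered 1 and 2 in both groups. The labels do not say whether the 2 numbers stand for separate cultures, so the spread between these libraries, given as SD, could be technical. The site test on summed counts covers counting error only, and the tests of gene lists are over genes. cutadapt and STAR are named in the submitters' processing notes. Their versions, the genome build, the site caller and its settings are not given in the sources used here.

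The deposited table lists 1892 positions with their strand and gene. For each of the 4 libraries it gives counts of covering reads and of mutated reads, per the file headers, and a deposited fraction that equals mutated over covering reads. The table does not name the mutated base. It also gives, per replicate, the authors' fold change as a ratio of the treated to the input fraction, and the authors' p-value and q-value. The table does not state how sites were chosen, and the following was tested on its values. Every site had at least 7.5% mutated reads and at least 10 mutated reads in both treated libraries, a treated-over-input ratio of at least 20.2 and a q-value of at most 0.00993. The deposited p-value was solved for the rate of a one-sided binomial test on the treated mutated reads. In replicate 1, 1832 of 1833 sites gave the same rate of 1.83% within 0.1%, and in replicate 2, 1851 of 1852 sites gave 1.81%. The 1 other site in each replicate gave its own input fraction. For 59 and 40 sites the deposited p-value was too small to solve. The quotient of q-value and p-value was constant within a chromosome to within 1.14%, as a multiplication by the number of positions tested there would give. No listed site fell below the ratio that these filters need at its coverage.

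Groups and replicate numbers came from the sample titles. The summed coverage over listed sites is not a library's depth, and the depth of the whole libraries is unknown here. Median coverage per site was 469 and 327.5 reads in treated replicates 1 and 2, and 417.5 and 338 reads in the input replicates. The lowest coverage of a site in any library was 43 reads. Wilson 95% intervals are given for single sites, with replicates summed. They cover counting error only, since the reads carry no stated molecular identifiers. A site without mutated reads has an upper limit of 3 reads over its coverage.

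The level of a site is the mean over the 2 replicates of its treated mutated fraction, and its difference subtracts the input fraction of the same number. Each site was tested with a two-sided Fisher exact test on mutated and unmutated counts summed over the replicates of each group, with Benjamini-Hochberg adjustment over sites and a minimum of 10 reads per group. The authors chose these sites on these libraries, so the test describes the list and is not independent evidence. Data were simulated with the real coverages of these 1892 sites and the real input rate. The test called 41.1% of sites changed 20-fold and 95.7% of those changed 100-fold, and 0 of 1692 unchanged sites. Unchanged treated sites were simulated at the input rate, which lies below the rates of 1.83% and 1.81% solved from the authors' p-values. The simulation therefore does not give the share of sites called at those rates. Gene lists were compared in their share of genes with a site, by Fisher exact test against all nuclear protein-coding genes, and in the level of their genes with a site, as the difference between the median of the list and that of the other genes, by a two-sided permutation test over genes with 100000 resamples and Benjamini-Hochberg adjustment over lists. The level of a gene was the mean over its sites of the difference from input. Simulated lists were drawn from 1240 genes with an SD of 1.78 points, without the genes with the largest differences. The permutation test was tested on these lists at an unadjusted p of 0.05. Of 100 lists shifted by 0.5 points it called 12 at 5 genes, 17 at 10, 27 at 18 and 49 at 40, and of 100 lists shifted by 1 point it called 21, 51, 83 and 99. Of 100 unchanged lists it called 11, 7, 3 and 7. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

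The gene lists, the tests, the main alternatives and the rule for named genes were fixed before the data were examined. The rule names the 10 genes with the most sites, the 10 genes holding the sites with the largest difference, the 5 holding those with the smallest, and in each list the 3 members with the most sites, with ties broken by level and then by name. The entry RPP1 was removed from the ribosomal protein list afterwards, because it names a subunit of ribonuclease P, and 2 list names without a matching symbol (ARG5,6 and FEN1) were not counted. Symbols were matched through a table of the R64 assembly: 1887 of 1892 sites had a matching locus tag. Of the other 5 sites, 3 were assigned to a pair of overlapping genes and were left out of counts per gene, and 2 keep the locus name of the deposited table. Positions are those of the deposited table. The build is not given, so sites were not placed in exons, untranslated regions or codons. No genome sequence was used here, and the planned comparisons of sequence context, codon, position along the coding sequence, level by region, and sites per cytidine were therefore not run. Genes of near-identical pairs, such as most ribosomal protein genes, can share reads, and how the authors treated such reads is not given in the sources used here. The alternatives were a Cochran-Mantel-Haenszel test with the replicate number as stratum, other coverage minimums, leaving out each replicate, stricter level thresholds, and leaving out paralog pairs. Further alternatives chosen after seeing the data are named as such in the closing section.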

Results

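Mutated reads at 1892 mRNA positions were measured in 2 libraries treated with pyridine borane and in 2 untreated input libraries of budding yeast. The positions lay on all 16 nuclear chromosomes, 953 on the plus and 939 on the minus strand, and each lay on the annotated strand of its gene. Coverage ranged from 57 to 184508 reads per site in treated replicate 1, from 44 to 129535 in treated replicate 2, from 51 to 159431 in input replicate 1 and from 43 to 132797 in input replicate 2. The table holds only positions that the authors had selected as high-confidence f5C sites in both replicates.

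The comparison of treated with input RNA asks how much higher the mutated fraction was after treatment at each site. The difference subtracts the input fraction only, and not the binomial rates of 1.83% and 1.81% solved from the authors' p-values. All 1892 listed sites had a higher mutated fraction after treatment, in both replicates. The most strongly mutated positions lay in RPS25A and RPS25B, a paralog pair that encodes a protein of the small ribosomal subunit. At the RPS25A site (YGR027C, chromosome VII, position 534477, minus strand) 98.7% and 99.3% of reads were mutated in treated replicates 1 and 2, at 398 and 277 covering reads, and the difference from input was 98.3 ± 0.0833 percentage points (SD, n = 2). At the RPS25B site (YLR333C, chromosome XII, position 795916, minus strand) the treated level was 79.3% ± 12.6 (SD, n = 2) at 98 and 68 covering reads, against 2.69% in input. The RPS25B input fractions of 2.15% and 3.23% were the highest of the list in input replicates 1 and 2, at 2 mutated reads each. Those of RPS25A were 0.518% and 0.935%. Reads of this pair can be shared between both genes. The next site, in the biotin transporter gene VHT1 (YGR065C, chromosome VII, position 619806, minus strand), reached 48.8% ± 10.6 (SD, n = 2), with 0 mutated reads in input, which allows an input share of up to 1.89%.

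The RPS25A and RPS25B sites stood apart from the rest of the list. With replicates summed, the Wilson 95% interval was 70.8% to 83.4% at RPS25B and 39.8% to 55.2% at VHT1, and the latter overlapped that of the RDH54 site, 25.2% to 43.3%. The median level was 8.75% in treated replicate 1 and 9.09% in treated replicate 2, and over the means of both replicates the quartiles were 8.35% and 10.1%. Levels under 10% were found at 1372 sites (72.5%), levels of at least 20% at 20 sites, and levels of at least 50% at the 2 RPS25 sites. In the input libraries 0.0473% and 0.0444% of the reads over these sites were mutated, and 1212 sites had no mutated read in either input library. The authors' p-values solve to binomial rates of 1.83% in replicate 1 and 1.81% in replicate 2, and the median treated level was 4.79 and 5.02 times these rates. What the rates were estimated from is not given in the sources used here. By Fisher exact test on summed counts all 1892 sites passed an adjusted p of 0.05, and the largest adjusted p was 1.55e-06. The smallest difference between treated and input was 7.33 percentage points.

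The other sites with the largest differences had levels of about 30% to 35%. Of the 337 sites with at least 1000 reads in every library, 0 had a level of 20% or more, so these high sites were all shallower. RDH54, which encodes a DNA translocase of recombinational repair, had a site at chromosome II position 383173 with a level of 35.0% ± 14.8 (SD, n = 2) at 57 and 44 treated reads. OSH7, a member of the oxysterol-binding protein family, reached 33.6% ± 1.69 at chromosome VIII position 106258, while its second site had 9.72%. Both ECM29 and BLM10 encode proteasome-associated proteins, and their highest sites had levels of 32.3% ± 2.24 (chromosome VIII, position 45045) and 32.0% ± 0.212 (chromosome VI, position 123665). The sites of VPS41, a subunit of the vacuolar tethering complex HOPS, of SFB3, a coat protein of transport vesicles, and of YGL140C had differences from input of 31.3 ± 8.11, 30.3 ± 4.00 and 29.8 ± 4.13 points. At the other end, the smallest differences lay in AVT3, a vacuolar amino acid transporter gene, with 7.33 ± 0.118 points, HBT1 with 7.48 ± 0.190, TMS1 with 7.49 ± 0.0781, WBP1, a subunit of the oligosaccharyltransferase, with 7.31 and 7.69 points in replicates 1 and 2, and AIM6 with 7.43 and 7.58. A single transcript could hold both kinds of site: HBT1 had 4 sites, and another of them, at chromosome IV position 59530, had a difference of 24.1 ± 7.67 points. All of these values are over n = 2 replicates.

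The median absolute difference in level between the treated replicates was 0.870 percentage points. Sites were listed only if they passed the minimum of 7.5% in both replicates, which leaves out sites whose replicates differ most, so the following values hold for selected sites. By two-sided Fisher exact test on the reads of each site, 52 sites (2.75%) differed between replicates at an unadjusted p of 0.05, and 0 differed after adjustment. The RPS25B site was among the 52, with 70.4% mutated reads in replicate 1 and 88.2% in replicate 2 (exact p = 0.00770, unadjusted). Across sites, which are not independent replicates, Pearson's r was 0.870 and Spearman's rho 0.465, each with a permutation p of 1e-04, the smallest that the permutations can give. Without the 3 highest sites Pearson's r was 0.734. Replicate 2 was higher at 1101 sites and lower at 791, with a median shift of 0.215 points. The level fell with coverage across sites (Spearman's rho = -0.499, permutation p = 1e-04), and the smallest ratio that passes the authors' filters is higher at shallow sites.

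**Figure D1:**
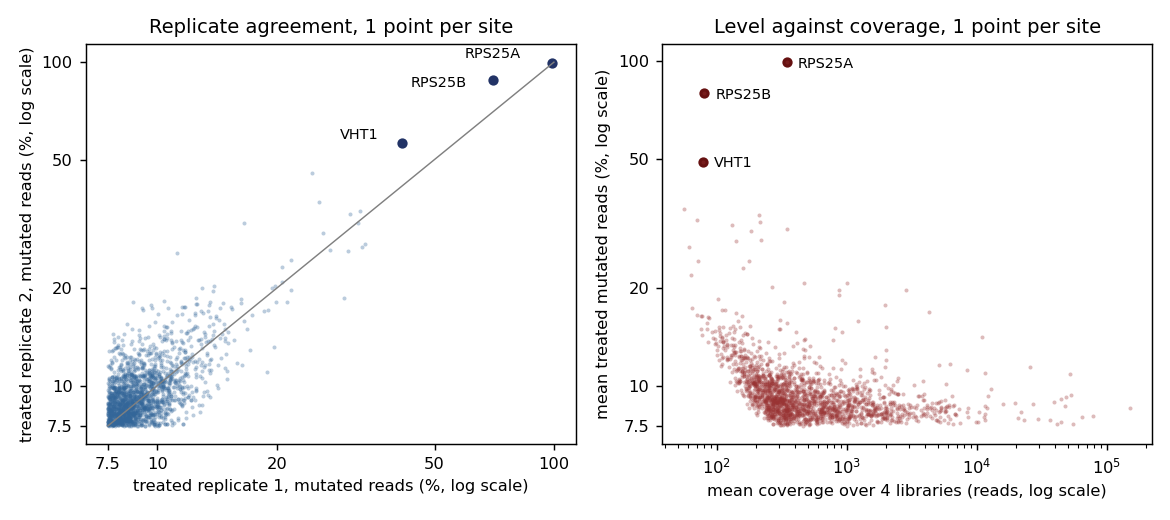
Left, mutated reads in percent in treated replicate 1 (x axis, log scale) and treated replicate 2 (y axis, log scale), 1 point per site, with the line of equality; right, the mean treated level in percent (y axis, log scale) against mean coverage over the 4 libraries in reads (x axis, log scale). Most of the 1892 sites lie between 7.5% and 10%, and the RPS25A, RPS25B and VHT1 sites, drawn larger, lie highest, the last 2 at 79.3% and 48.8%.

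The next comparison asks which transcripts carried the sites. Sites assigned to a single gene fell in 1253 genes. Of these, 828 genes had 1 site, 425 genes (33.9%) had more than 1, and 46 genes had 4 or more. ACC1, the acetyl-CoA carboxylase that starts fatty acid synthesis, and HSP104, a disaggregase of heat-shocked cells, had 8 sites each, with mean differences from input of 9.32 ± 0.0212 and 8.49 ± 0.133 points (SD, n = 2). KGD1, a subunit of the alpha-ketoglutarate dehydrogenase of the tricarboxylic acid cycle, and PHM7 had 7 sites each. The KGD1 sites ranged from 8.15 to 20.7 points. HOL1 had 6 sites, and 5 sites each were found in CAT2, a carnitine acetyltransferase, in GDB1, the glycogen debranching enzyme, in the aconitase gene ACO1, and in NST1 and AIP5. Across these 1253 genes the number of sites rose weakly with the mean coverage of the listed sites (Spearman's rho = 0.175, permutation p = 1e-04). Genes without a site were left out, so this value does not describe how site number depends on coverage over all genes. Gene length and the number of cytidines per gene were not used in this ranking. Per 1000 tests implied by the quotient of the authors' q-values and p-values in replicate 2, chromosomes held between 3.78 sites (chromosome IV) and 5.31 sites (chromosome VIII). These densities did not differ by a Monte Carlo chi-square test over the 16 chromosomes (p = 0.254). No site was assigned to a mitochondrially encoded or non-coding RNA gene.

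Genes with a site were more frequent in 12 of 14 gene lists than among all nuclear protein-coding genes, of which 1251 of 6002 (20.8%) had a site. The highest share was found in glycolysis and ethanol fermentation, with 18 of 25 genes (odds ratio 9.89, Fisher exact test with Benjamini-Hochberg adjusted p = 3.69e-07). Its members with the most sites were PDC1, the main pyruvate decarboxylase, with 4 sites, and GLK1, a glucokinase, and PFK2, a phosphofructokinase subunit, with 3 each. Chaperones and heat shock proteins followed with 17 of 29 genes (adjusted exact p = 4.41e-05), among them HSP104, HSC82 with 5 sites and the ribosome-associated chaperone SSB1 with 4. In amino acid and one-carbon biosynthesis 37 of 69 genes had a site (adjusted exact p = 2.34e-08), with 4 sites in the histidine synthesis gene HIS4, 3 in the glutamate dehydrogenase gene GDH3 and 3 in ARO4 of aromatic amino acid synthesis. In lipid and sterol synthesis 20 of 39 genes had a site (adjusted exact p = 8.27e-05), with 3 sites each in HMG2 and ERG2 of the sterol pathway besides the 8 in ACC1.

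Lists of protein synthesis and turnover also held more genes with a site than the genome at large. Among translation factors the count was 15 of 35 (adjusted exact p = 0.00674), with 3 sites each in EFT1, CAM1 and YEF3, which encode elongation factors. Aminoacyl-tRNA synthetases had 10 of 21 (adjusted exact p = 0.00853), with 2 sites each in SES1, VAS1 and GUS1. The proteasome and ubiquitin list had 18 of 39 (adjusted exact p = 0.00124), with 3 sites in the ATPase gene CDC48 and 2 each in RPN12 and RPN1. Cytosolic ribosomal proteins had 43 of 137 (adjusted exact p = 0.00676), a share of 31.4%. RPS8A had 3 sites, and RPL4A and RPL4B, a paralog pair, had 2 each. In both RPL4 genes the sites lay 4 nt apart, with differences from input of 7.99 and 11.6 points in RPL4A and 8.81 and 11.9 points in RPL4B. Of the list members named, RPS8A, RPL4A, RPL4B, PDC1, EFT1, HSC82, SSB1, HXT7, IMD4, HTA2 and HHT2 have near-identical paralogs, with which they can share reads.

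The share was also higher in plasma membrane transporters and pumps, with 16 of 38 genes (adjusted exact p = 0.00676) and 4 sites in the drug exporter gene PDR5, 3 in the arginine permease gene CAN1 and 3 in HXT7, in tricarboxylic acid cycle and respiration with 17 of 47 (adjusted exact p = 0.0242) and 4 sites in SDH1, in cell wall and secreted proteins with 13 of 35 (adjusted exact p = 0.0429) and 3 sites each in YPS1, SCW10 and SIM1, and in histones with 5 of 10 (adjusted exact p = 0.0450) and 1 site each in HTA2, HHO1 and HHT2. Of the other lists, actin, tubulin and septins had 7 of 20 genes (adjusted exact p = 0.162), with 2 sites in ABP1, 2 in ACT1 and 1 in CDC11. Ribosome biogenesis had 4 of 40 (adjusted exact p = 0.125), with 1 site each in IMD4, RLI1 and MRT4. Without genes of near-identical pairs, where fewer genes were tested, translation factors (adjusted exact p = 0.0778) and histones (adjusted exact p = 0.367) no longer passed. The odds ratio went from 2.87 to 2.06 in translation factors and from 3.81 to 3.90 in histones. In cytosolic ribosomal proteins, where 9 genes with a site remained, it went from 1.76 to 3.53 (adjusted exact p = 0.0132). The genes with a site had a median coverage of 359 reads over all genes, 10866 in glycolysis, 2930.5 in chaperones, 2445 in ribosomal proteins, 578 in amino acid biosynthesis and 358.5 in plasma membrane transporters, the list of the 12 whose value was not above that over all genes. No coverage of genes without a site was used here, and no gene length or number of cytidines. A higher share in these lists is therefore not separated from higher expression or longer genes.

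**Figure D2:**
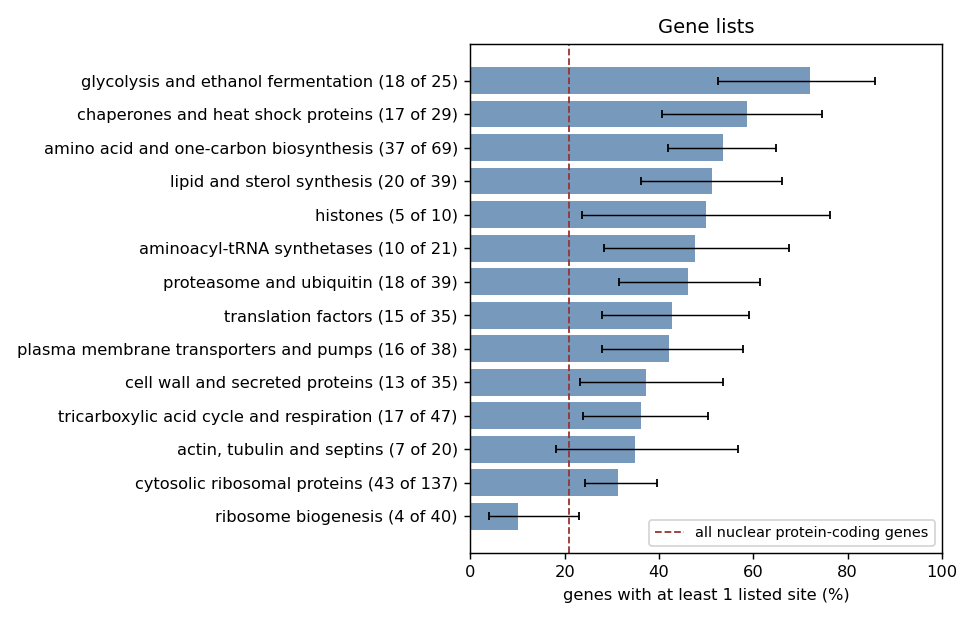
Percent of the genes of each list with at least 1 listed site (bars, x axis), with Wilson 95% intervals over genes and the number of genes beside each name; the dashed line is the 20.8% of all nuclear protein-coding genes. Glycolysis and ethanol fermentation has the longest bar, with 18 of 25 genes, and ribosome biogenesis, with 4 of 40, lies left of the line.

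The lists were also compared in the size of the difference from input per gene. By permutation test of the medians 0 of 14 lists differed from the other genes with a site after adjustment, and 1 list passed an unadjusted p of 0.05. For simulated lists of 10 genes the same test called 51 of 100 lists shifted by 1 point at an unadjusted p of 0.05, and for lists of 5 genes 21 of 100. Differences of this size in the smaller lists were thus often not detectable. At a shift of 0.5 points it called 27 of 100 lists of 18 genes and 49 of 100 lists of 40 genes, so such differences were often missed in larger lists too. Adjustment over lists, which was not simulated, is stricter. The list that passed was the cytosolic ribosomal proteins, whose median over 43 genes was 8.52 points against 9.09 in the other genes (difference -0.575 points, permutation p = 0.0247, adjusted p = 0.346). Within 5 classes of coverage, a comparison chosen after seeing the data, the difference of the medians was -0.0263 points (permutation p = 0.787, adjusted p = 0.968). The means had the opposite order, 12.3 against 9.80 points, and RPS25A and RPS25B set it: without this pair the mean of the list was 8.59 points. In the remaining lists the medians ran from 8.23 points in actin, tubulin and septins to 9.86 points in the 4 genes of ribosome biogenesis. The latter was 9.25 points in the 3 genes left without paralog pairs, which leaves out IMD4.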

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

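Alternatives chosen after seeing the data were the minimum of 1000 reads and the removal of the highest sites or of RPS25A and RPS25B. So were the comparison within 5 classes of coverage, the difference of means between lists, the level without subtracting input, and those on gaps and chromosomes. The plan named medians for the level of lists. The difference of means was computed first, however, and its result of 0 of 14 lists was seen before the medians were run. The count of 1892 sites higher in treated RNA was the same under coverage minimums of 20 reads, 50 reads and none, which removed no site, and with either replicate left out. The authors had selected every site in both replicates, which fixes these counts, so they say nothing about stability. Labels give treated and input libraries the same numbers, but nothing says that a number marks a shared culture, and deviations of same-numbered libraries correlated at -0.00502 for coverage over 1892 sites and 0.161 for the mutated fraction over 85 sites; the Cochran-Mantel-Haenszel test with the replicate number as a block called 1892 sites and changed no call, with the same limit. The median level ranged from 8.75% to 9.09% when a replicate was left out and was 8.49% at sites with at least 1000 reads in every library, where fewer shallow sites with a high required ratio remain. Spearman's rho between treated replicates was 0.463 to 0.490. The number of genes with a site, 1253, was 755 in the upper 50% of sites by level and 20 at levels of at least 20%, by construction of these thresholds, and 1192 without paralog pairs. The number of lists with a different level was 0 in every comparison of medians and 1 by difference of means within classes of coverage, where ribosomal proteins lay 3.40 points above other genes (adjusted permutation p = 0.000700, range over the alternatives 0.000700 to 0.968), while the difference of medians within the same classes was -0.0263 points (permutation p = 0.787), against -0.575 points without classes. The mean difference of this list was 2.45 points without classes and -1.22 points without RPS25A and RPS25B, so this pair carries it. Histones had too few genes for a comparison of levels without paralog pairs. The number of lists with a higher share of genes with a site was 12, and 10 without paralog pairs. The alternatives for sequence context, codon, position along the coding sequence and level by region were not run, because no genome was used here. Under 200 reads of mean coverage the filters need a median ratio of 9.77%, against 7.52% from 1000 reads, so weaker sites in less abundant transcripts were not detectable at this depth.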

Other observations

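All tests of this part were chosen after the data had been seen. The genes with the most sites included GDB1 of glycogen breakdown and CAT2 of acetyl-carnitine transport, and 5 further lists were written after the sites per gene had been seen. In storage carbohydrate metabolism 15 of 17 genes had a site (odds ratio 28.8, adjusted exact p = 4.79e-08), among them the glycogen synthase genes GSY1 and GSY2, the glycogen phosphorylase gene GPH1 and TPS2 and TSL1 of trehalose synthesis. In the list of vacuolar hydrolases 10 of 11 had a site (adjusted exact p = 6.38e-06), including the protease genes PEP4, PRB1 and PRC1, and VTC4, which encodes a polyphosphate polymerase and no hydrolase. In gluconeogenesis, the glyoxylate cycle and acetate use the count was 10 of 20 (adjusted exact p = 0.00667), including both pyruvate carboxylase genes PYC1 and PYC2. Cyclins and cell cycle kinases had 1 of 18 (adjusted exact p = 0.164), which was CLN3, and peroxisomal beta-oxidation 1 of 12 (adjusted exact p = 0.480), which was PEX11. In the first of these lists, genes with a site had a median coverage of 1540 reads, against 359 over all such genes. Neither expression nor gene length is separated from site density here. Since these lists were prompted by the same sites, their counts are a hypothesis and not independent evidence.

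The RPS25A and RPS25B sites stood above all others. Counting error at low depth does not account for the gap, since the lower 95% limit of the RPS25B site lay 15.6 percentage points above the upper limit of the next site. These limits sum the replicates and leave out the spread between them. In treated replicates 1 and 2 the levels were 70.4% and 88.2% at RPS25B, and 41.3% and 56.25% at VHT1. A strain variant would show in untreated RNA. The input share at RPS25B was the highest of the list in both input libraries, but at most 6.45% (upper 95% limit). However, every listed site had a treated-over-input ratio of at least 20.2. A variant with like shares in both groups could therefore not enter the list. The treated counts of both sites differed (two-sided Fisher exact p = 2.85e-21, replicates summed). If a mutation does not change which gene a read is assigned to, not every RPS25B read came from RPS25A. How shared reads were assigned is not given, so this test cannot exclude that they did. Most of them may have, and a single modified site in RPS25A stays open. The design gives no biological contrast for these sites, and no biological explanation was tested.

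Most levels lay just above the 7.5% minimum and fell with coverage. Among the 337 sites with at least 1000 reads in every library, 61 had levels in the narrower class of 7.5% to 8% (122 per percentage point), 192 had levels of 8% to 9%, 49 of 9% to 10% and 19 of 10% to 11%, a quotient of 0.255 between the classes at 9% to 10% and at 8% to 9%. Whether these are the upper tail of a continuous spread of conversion or many weakly modified sites stays open, since the class nearest the minimum was thinner than the next, the minimum applied to both replicates, and positions below it were not used here. Subtracting the smallest ratio that passes the filters at each coverage brought the correlation with coverage from -0.499 to -0.144 (95% interval -0.187 to -0.0994). That ratio itself falls with coverage, so subtracting it weakens such a correlation whatever the cause. How much the significance filter accounts for therefore stays open. The median excess over the ratio was 1.52 points under 200 reads of mean coverage and 1.01 points from 1000 reads. Whether sampling noise adds to the fall with coverage stayed open as well. The correlation at the 337 deep sites was -0.120 (95% interval -0.228 to -0.0136), which met the bound set beforehand against noise. That bound was wrong, since a counting SD of 0.413 points is still large beside their interquartile range of 0.863 points.

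Neighbouring sites of a gene lay 1 to 4 nt apart more often than an even spread of gaps gives: 43 of the 74 gaps of 1 to 20 nt (58.1%, exact 95% interval 46.1% to 69.5%, against 20%; exact binomial p = 7.02e-13), with 10, 12, 16 and 5 pairs at gaps of 1, 2, 3 and 4 nt. Reads shared between the listed paralog pairs do not account for it, since the share was 58.5% without them (exact 95% interval 45.6% to 70.6%). Misaligned reads stay open: the input fraction of the 85 sites in close pairs exceeded that of other sites by 0.00260 points (95% interval -0.00840 to 0.0146), but every listed site had a treated-over-input ratio of at least 20.2, so sites with input near the treated level could not enter this comparison. A local property of the RNA shared by neighbouring cytidines could account for it, and levels of close pairs correlated at a rho of 0.271 against -0.0165 in 116 pairs 5 to 100 nt apart, but this difference of 0.288 missed the threshold (one-sided permutation p = 0.0531). The distribution of cytidines around the sites was not used here, so the even spread is an assumption.

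Gaps between neighbouring sites of a gene were a multiple of 3 nt in 215 of 636 pairs (33.8%, exact 95% interval 30.1% to 37.6%, against 33.3%; exact binomial p = 0.801), so no preferred reading-frame spacing was detectable with this number of pairs.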
